A study of Homo sapiens with 11 samples.

How the data were processed

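RNA was measured in 11 endometrial biopsies, which were flash-frozen, purified with a column kit and made into stranded libraries after removal of ribosomal RNA, per the labels' protocols. Phase was taken from the phase label of each sample, giving 6 proliferative and 5 mid-secretory libraries. Replicates were numbered in accession order within each phase, and these numbers pair no samples. The sample titles also hold a number, 1 or 2, of unstated meaning, which was used only as a possible batch.

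The values are raw read counts per gene, deposited by the authors in a single table laid out as featureCounts writes it, per the file headers. Reads were aligned to GRCh38.p10 with HISAT2 2.0.3 and summarised with featureCounts, with edgeR also named, per the submitters' processing notes. The strand setting, the treatment of reads that fit several places and the annotation release are not given in the sources used here. The table lists 58233 genes by Ensembl identifier. Of these, 57895 were named from GENCODE release 29 (Ensembl 94, GRCh38), 338 had no name there, and 99.998% of gene lengths equalled the length of the merged exons in that annotation. Unnamed genes held at most 0.0295% of the counts of any library, and no column of the table was left unused. XIST, TSIX and genes on the Y chromosome, 521 in all, were left out of all tests.

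Libraries held between 31.3 and 65.0 M (mega) counts. Because counts are used, the smallest detectable level differs between libraries: 3 counts correspond to 0.0461 to 0.0957 CPM. Without known settings for strand and for reads shared between genes, genes with near-identical copies or overlapping exons are uncertain. For the 121 named genes, all 50-base windows of their annotated transcripts were searched in the transcripts of all other annotated genes. Of these genes, 4 had fewer than 50% and 8 fewer than 80% of windows unique. Exon overlap over 20% was found on the same strand for 1 and on the other strand for 4 of the named genes.

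Differences were tested with edgeR 4.0.16 (quasi-likelihood test, TMM factors, filterByExpr) in R 4.3.3, with no covariate, Benjamini-Hochberg adjustment and a threshold of 0.05 for adjusted p. The expression filter left 21003 genes and removed 36709, and in the library with the smallest share the tested genes held 99.88% of the counts. The biological coefficient of variation was 31.6% and the median change of all tested genes was 0.01 on the log2 scale. Intervals are 95% intervals of the fitted change, and log2 CPM used a prior count of 2. Gene lists with at least 3 tested members, 34 in all, were compared with all other genes by camera in limma 3.58.1 with a preset correlation of 0.01, and again with an estimated correlation and with fry, which tests the members of a list without the other genes, and adjusted over the lists. The design, the lists, the rule for named genes and the alternatives were fixed before the data were examined, except where a choice is said to have been made later.

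The rule for named genes took FOXA2, ESR1 and PGR, then the 8 highest and 8 lowest changes among protein-coding genes past the threshold with at least 1 CPM in the higher group and no overlap between phases, and then up to 2 members per direction of each list with the smallest adjusted p (where none passed, the 2 with the highest CPM). A few further list members are named in the text after their values were seen, each said to be so. Duplicate libraries were looked for by comparing all pairs: the smallest chi-square per gene within a phase was 45.9, far above the value of 1 that sampling noise gives, so no libraries were merged.

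Alternatives were DESeq2 size factors, the DESeq2 1.42.0 Wald test, no filter beyond 1 count in total, a filter of at least 1 CPM in 5 libraries, title number as a covariate, each title number alone, a 2-fold minimum, limma-voom with quality weights, leaving out each library, and for lists an estimated correlation and fry. Library sizes without mitochondrially encoded genes were added after the data were seen. Alternatives meant for normalized values were not run because the table holds counts.

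The tests were tested on simulated data, with counts drawn for 21003 genes from the proliferative means and the real library sizes. The spread of each gene followed the fitted trend with expression level, and 200 genes were changed. These are far fewer than the genes called in the real comparison, so adjustment was stricter in the simulation. The recovered shares below hold for that setting only. At 6 against 5 libraries edgeR recovered 5.97% of 1.5-fold, 70.1% of 2-fold and 97.0% of 4-fold changes with 9 false calls. DESeq2 recovered 10.4%, 74.6% and 97.0% with 37 false calls, and limma-voom 4.48%, 65.7% and 97.0% with 7. Among simulated lists, 2 of 2 changed lists and 0 of 10 unchanged lists were called by camera, with a preset or an estimated correlation, and by fry, at adjusted thresholds. Each gene was drawn independently, so the simulated lists held no correlation between members. They cannot show how often camera makes false calls on lists of correlated genes, such as the cell cycle list (estimated correlation 0.67). Exact permutation tests ran over all 462 assignments of the 11 libraries, so the smallest p they can give is 0.00216. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for sequence searches and figures.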

Results

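Human endometrium, the inner lining of the uterus, was profiled by RNA sequencing in 11 biopsies, 6 labelled as proliferative phase and 5 as mid-secretory phase. The proliferative phase is the growth phase of the menstrual cycle, and the mid-secretory phase falls after ovulation, when the lining becomes receptive to an embryo. In units of M (mega) counts, libraries held 40.6 ± 2.87 M (SD, n = 6; range 36.4 to 44.8 M) in the proliferative group and 47.8 ± 15.9 M (SD, n = 5; range 31.3 to 65.0 M) in the mid-secretory group. Protein-coding genes took 96.0% ± 0.585 (SD, n = 6) of counts in proliferative and 96.0% ± 0.348 (SD, n = 5) in mid-secretory libraries. At these depths a count of 0 allows at most 3 counts, which is between 0.0461 and 0.0957 counts-per-million (CPM) depending on the library. Such floors and counting intervals cover counting error only. The labels state neither pairing nor whether the biopsies came from separate donors, so p-values measure the spread between these samples. The sample titles carry a number, 1 or 2, whose meaning the labels do not give. Title number 1 held 4 proliferative and 3 mid-secretory libraries and title number 2 held 2 of each, so differences were also computed within each number. Unless stated otherwise, changes are mid-secretory minus proliferative on the log2 scale ± SE, tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment. The SE was derived from the change and the F statistic of that test, and is approximate for genes with few reads in 1 phase.

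The comparison of the phases asks which transcripts differ between growing and receptive endometrium. The series concerns FOXA2, a forkhead transcription factor of the endometrial glands, and its transcript is reported first. FOXA2 (ENSG00000125798; GRCh38 chromosome 20, 22581005 to 22585455, minus strand) was present at 26.1 ± 6.61 CPM (SD, n = 6) in proliferative and 21.6 ± 5.07 CPM (SD, n = 5) in mid-secretory biopsies. The difference of -0.27 ± 0.19 (95% interval -0.68 to 0.14) did not pass the test (adjusted p = 0.309). An exact permutation test of mean log2 CPM over all 462 assignments, which takes both directions, gave a difference of -0.26 with p = 0.229. Within title number 1 the FOXA2 difference was -0.07 ± 0.23 (adjusted p = 0.858) and within title number 2 it was -0.63 ± 0.27 (adjusted p = 0.162). Leaving out each library in turn moved it between -0.44 and -0.13 without a call, the smallest size being that without proliferative replicate 5 and the largest that without mid-secretory replicate 1.

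Of the receptors for the ovarian steroids, ESR1 and PGR fell. ESR1, the main oestrogen receptor (ENSG00000091831; chromosome 6, 151656691 to 152129619, plus strand), fell by 1.76 ± 0.15 (adjusted p = 6.65e-07), from 700.2 ± 125 CPM (SD, n = 6) to 207 ± 19.5 CPM (SD, n = 5). PGR, the progesterone receptor (ENSG00000082175; chromosome 11, 101029624 to 101130524, minus strand), fell by 2.45 ± 0.18 (adjusted p = 2.5e-07), from 1159 ± 268 to 213 ± 27.9 CPM. Both fell within each title number, ESR1 by 1.83 ± 0.19 and 1.60 ± 0.17 and PGR by 2.58 ± 0.21 and 2.13 ± 0.18. Among 14 steroid receptors and co-chaperones 3 rose, 5 fell and 6 did not pass, with the same counts adjusted over the list alone, and as a set the list did not pass by camera (adjusted p = 0.302) but was lower by fry (adjusted p = 0.0175). The other members that fell were the androgen receptor AR, the membrane oestrogen receptor GPER1 and PGRMC1. Those that rose were ESR2, the second oestrogen receptor, by 3.39 ± 0.26 from 0.596 ± 0.149 to 6.24 ± 1.66 CPM, the co-chaperone FKBP5 by 3.44 ± 0.26, and the coactivator NCOA3 by 0.69 ± 0.14. Of 20 oestrogen-responsive genes 3 rose, 13 fell and 4 did not pass (3 and 14 adjusted over the list alone), and the list was lower as a set (camera adjusted p = 8.52e-05; adjusted p = 0.0413 with an estimated correlation). SFRP4, a secreted WNT antagonist, fell by 5.41 ± 0.39 from 5875 ± 2243 to 138 ± 72.1 CPM, the matrix metalloproteinase MMP11 fell by 4.73 ± 0.43, and OLFM1 fell by 3.81 ± 0.23. SLC7A2, a transporter of basic amino acids, rose by 2.10 ± 0.15, MYC by 0.98 ± 0.24 and XBP1, a regulator of secretory protein folding, by 0.56 ± 0.14. XBP1, NCOA3, AR, GPER1 and PGRMC1 are list members named after their values were seen.

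**Figure D1:**
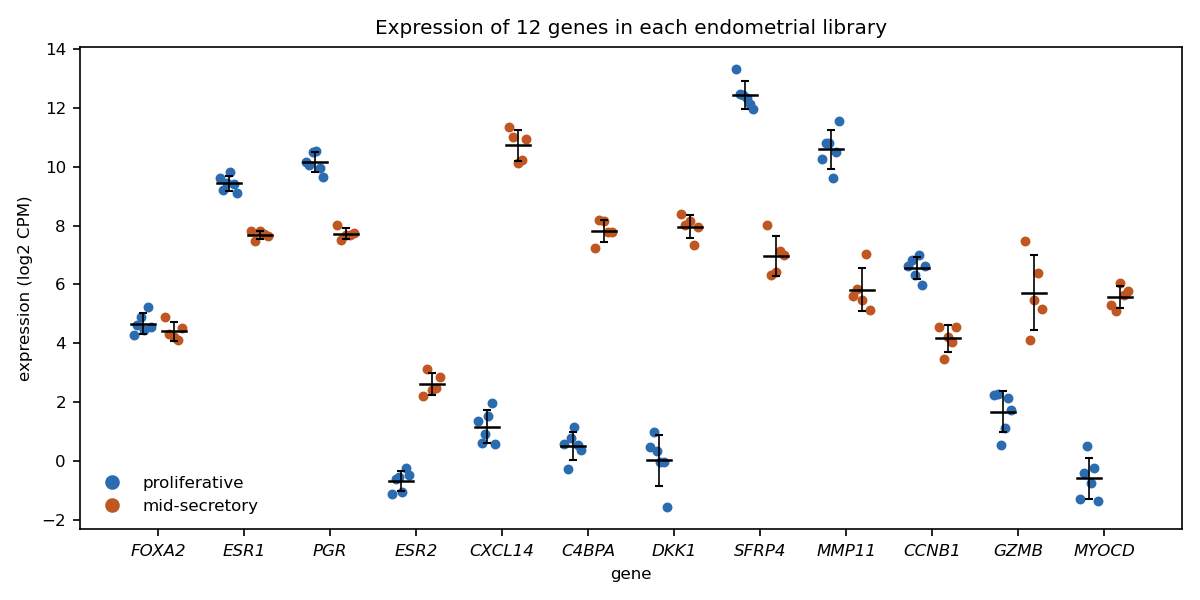
Expression as log2 CPM of 12 genes in each of the 6 proliferative and 5 mid-secretory libraries, with points for libraries and bars for the mean and SD. FOXA2 points of the phases overlap, whereas ESR1 and PGR are lower and CXCL14 is higher in every mid-secretory library.

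Over the transcriptome, 3767 of 21003 tested genes (17.9%) were higher and 3687 (17.6%) lower in mid-secretory endometrium. Of 15429 tested protein-coding genes, 3155 were higher and 2985 lower. At least a 4-fold change was reached by 867 of the higher and 894 of the lower genes, and at least a 16-fold change by 234 and 154. The libraries of the phases did not overlap for 4848 genes (23.1%), against 0.433% by chance. Within title number 1 the test called 2730 genes higher and 2575 lower, and within title number 2 it called 2117 and 1986. Over all 20591 genes tested in both, the changes within the title numbers had a Pearson correlation of 0.864 across genes, which are not independent replicates. No gene passed edgeR's test of whether the phase difference itself depended on title number (0 genes; 778 at an unadjusted p under 0.05; 4 genes by DESeq2). The first principal component took 58.9% of the variance and separated the phases, and component 2 took 9.60%. Within each phase, the libraries of title number 2 lay below those of title number 1 on component 2. Pearson correlations of log2 CPM across genes, which are not independent replicates, were 0.957 to 0.980 within proliferative, 0.955 to 0.980 within mid-secretory and 0.885 to 0.916 between phases.

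**Figure D2:**
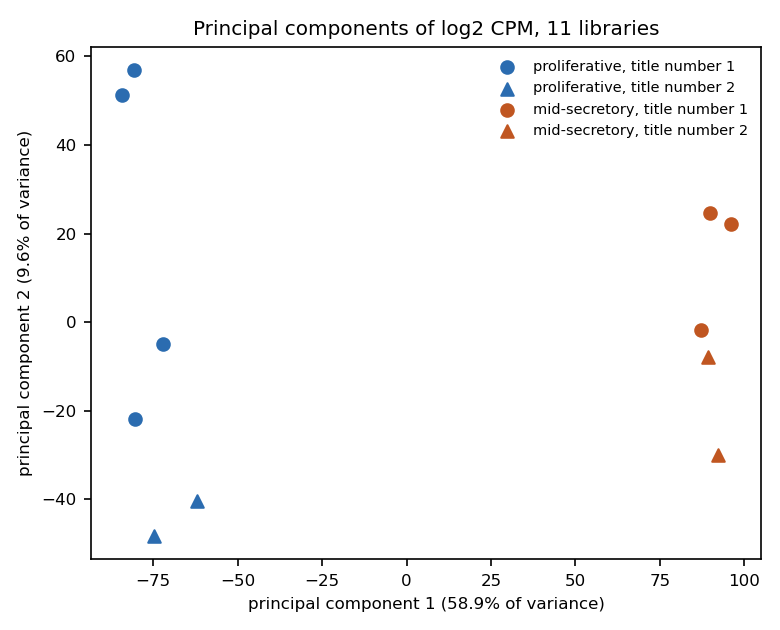
Principal components of log2 CPM in the 11 libraries, with percent of variance on each axis, colour for phase and marker shape for the number in the sample title. Proliferative and mid-secretory libraries lie apart on component 1, which takes 58.9% of the variance.

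The largest rises among protein-coding genes whose libraries did not overlap were those of GAST, COMP, PLA2G2A, TEX101, TCN1, CXCL14, ADGRF1 and C2CD4A. CXCL14, a chemokine (chromosome 5, 135570679 to 135579279), rose by 9.58 ± 0.38 (adjusted p = 1.26e-09), from 2.34 ± 0.952 CPM (SD, n = 6) to 1787 ± 622 CPM (SD, n = 5). C2CD4A (chromosome 15, 62066977 to 62070917) rose by 9.34 ± 0.31 (adjusted p = 3.75e-10), to 444 ± 49.5 CPM. TCN1, a vitamin B12 binding protein, rose by 9.65 ± 0.67 to 231 ± 165 CPM, and COMP, a matrix protein of cartilage, by 10.38 ± 0.56 to 198 ± 135 CPM. GAST, which encodes the hormone gastrin, rose by 11.79 ± 0.66 to 64.2 ± 40.2 CPM, with 4 reads over the 6 proliferative libraries, and by 13.01 without proliferative replicate 4. The proliferative libraries held 7 reads of PLA2G2A, a secreted phospholipase, and 5 of TEX101, so the sizes of these rises rest on few counts. The largest falls were those of ETNPPL, DAPL1, ASIC2, SDK2, RIMS4, WIF1, TRH and PCDH8. SDK2, a cell adhesion molecule (chromosome 17, 73334384 to 73644089), fell by 6.64 ± 0.28 (adjusted p = 1.72e-09), from 66.7 ± 13.3 to 0.660 ± 0.256 CPM, and the acid-sensing channel ASIC2 fell by 6.96 ± 0.36 from 22.9 ± 2.70 to 0.193 ± 0.113 CPM. ETNPPL, an enzyme of phosphoethanolamine breakdown, fell by 7.82 ± 0.44, with 6 reads over the 5 mid-secretory libraries. TRH, which encodes thyrotropin-releasing hormone, fell by 6.14 ± 0.75 (7.04 without mid-secretory replicate 2) and the secreted WNT inhibitor WIF1 by 6.35 ± 0.85. DAPL1 had 577 proliferative reads and 2 mid-secretory reads, a ratio, scaled to library size, of 283 (counting interval 78.0 to 2341). Without mid-secretory replicate 2 no mid-secretory read of DAPL1 was left, and against a floor of 3 counts over the group it was at least 137-fold lower. In DAPL1, 70.8% of 50-base windows were found in no other annotated gene and 30.3% of exon bases overlapped another gene on the same strand, so its reads are uncertain.

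Genes of cell division fell as a group. All 35 cell cycle genes fell, over all genes and adjusted over the list alone, and the list was lower as a set (camera adjusted p = 5.08e-23; adjusted p = 0.147 with an estimated correlation). CCNB1, the mitotic cyclin B1, fell by 2.38 ± 0.23 from 97.3 ± 23.6 to 18.7 ± 5.31 CPM. MCM2, part of the replicative helicase, fell by 1.82 ± 0.18; 23.6% of its exon bases overlap a gene on the other strand. The proliferation marker MKI67 fell by 2.50 ± 0.33 and the topoisomerase TOP2A by 3.08 ± 0.35, both named after their values were seen. All 35 fell within title number 1 and 34 within title number 2. Of 28 replication-dependent histone genes only 5 were expressed highly enough to test, of which 1 rose (HIST1H1C), 2 fell (HIST1H2BH and HIST1H3G) and 2 did not pass, the same adjusted over the list alone (camera adjusted p = 0.326; lower by fry, adjusted p = 0.0268). HIST1H3G stood near the expression filter and was not tested when proliferative replicate 1, 2, 3, 4 or 6 was left out, and 1 histone gene then fell.

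Genes reported to mark the receptive endometrium rose almost without exception. Of 40 such genes 38 rose, 1 fell and 1 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 3.68e-32; adjusted p = 0.0021 with an estimated correlation). C4BPA, an inhibitor of complement, rose by 7.32 ± 0.27 from 1.46 ± 0.465 to 233 ± 57.0 CPM, and SLC1A1, a glutamate transporter, rose by 4.85 ± 0.18 from 18.0 ± 4.22 to 517 ± 53.4 CPM. PAEP, which encodes the secreted gland protein glycodelin, rose by 7.23 ± 0.68 to 9834 ± 3767 CPM, the osteopontin gene SPP1 by 5.87 ± 0.38, and the cytokine gene LIF by 3.61 ± 0.35; these were named after their values were seen. HEY2, a Notch target, fell by 2.91 ± 0.24, and SCGB1D2 did not pass at 1.05 ± 0.67. Within title number 1, 38 rose and 1 fell, and within title number 2, 37 and 1. Such lists were first drawn from comparisons of these phases in other samples. The decidualization list, genes of the stromal change that prepares for pregnancy, had 21 of 29 higher, 4 lower and 4 not passing, the same adjusted over the list alone (camera adjusted p = 6.48e-07; adjusted p = 0.0134 with an estimated correlation). The scavenger receptor SCARA5 rose by 6.57 ± 0.32 and the transcription factor CEBPD by 3.74 ± 0.23, while DIO2, which activates thyroid hormone, fell by 3.04 ± 0.26 and GATA2 by 1.79 ± 0.17. HOXA10 and HOXA11 were the other members that fell, and within the title numbers 20 and 17 members rose and 4 and 2 fell.

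**Figure D3:**
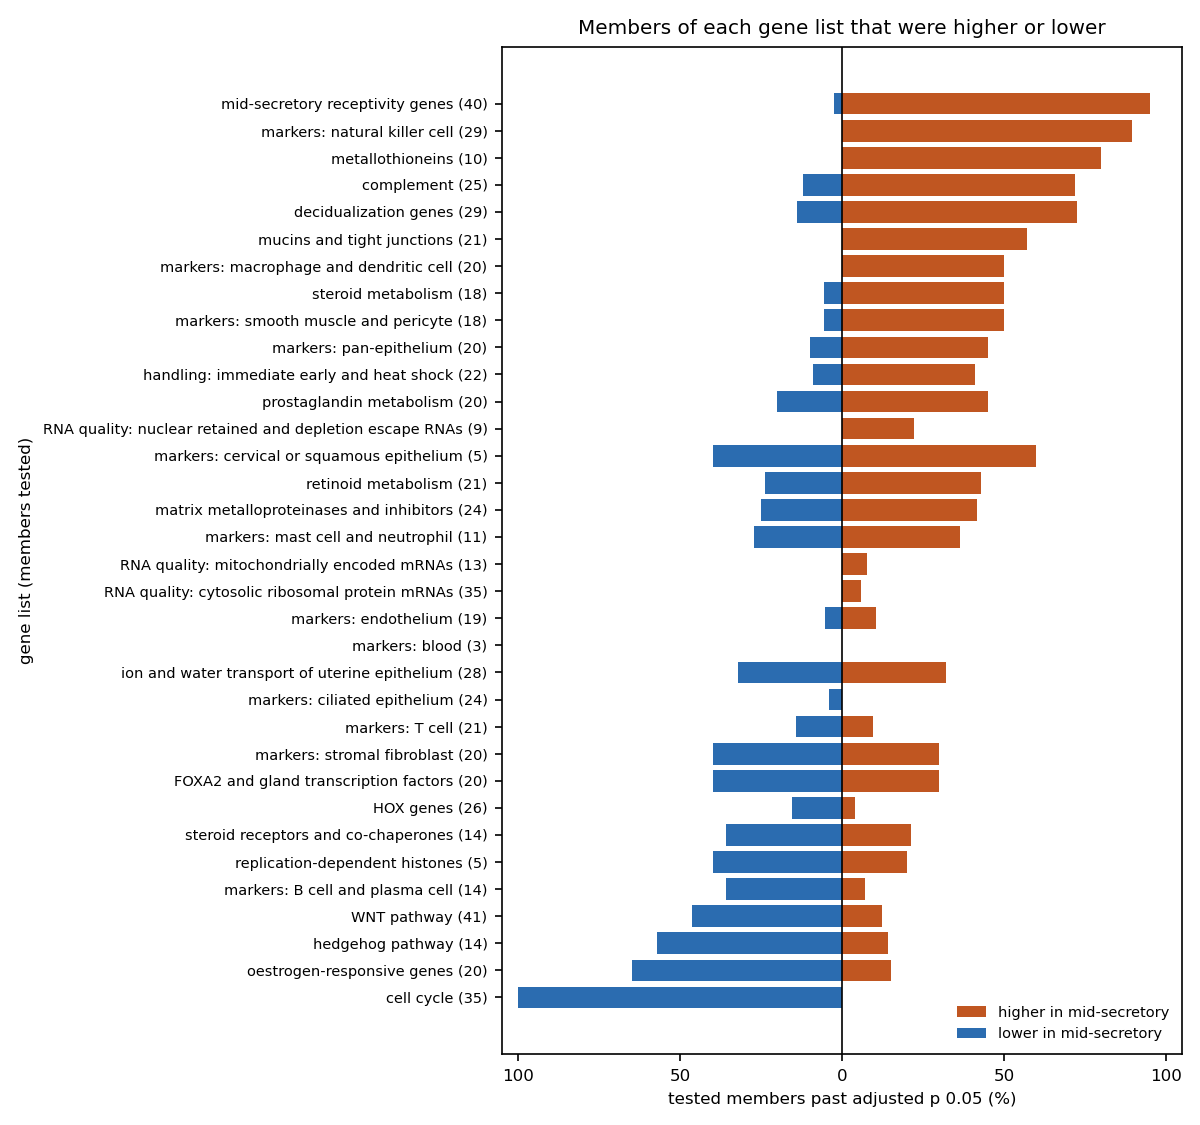
Tested members of each of the 34 gene lists that passed edgeR's test, as percent of the members tested (number in brackets), with those higher in mid-secretory endometrium to the right of 0 and those lower to the left. The receptivity list had 38 of 40 members higher and the cell cycle list had 35 of 35 lower.

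Gland transcription factors moved in both directions around FOXA2. Of 20 tested members 6 rose, 8 fell and 6 did not pass, the same adjusted over the list alone (camera adjusted p = 0.663). PAX8 rose by 2.60 ± 0.16 from 108 ± 24.8 to 657 ± 33.9 CPM and HNF1B by 2.55 ± 0.15, whereas the homeobox gene MSX2 fell by 3.85 ± 0.24 and SOX17 by 2.64 ± 0.20. SPDEF, a factor of secretory cells named after its values were seen, fell by 5.70 ± 0.52. The pan-epithelial marker list moved with the phases beside these genes: 9 of 20 rose, 2 fell and 9 did not pass, the same adjusted over the list alone (camera adjusted p = 0.0283; adjusted p = 0.709 with an estimated correlation). That set call was lost without proliferative replicate 1 (adjusted p = 0.098) and without mid-secretory replicate 2 (adjusted p = 0.0965), and within title number 2 (adjusted p = 0.159). Without proliferative replicate 2, 3 or 5 or mid-secretory replicate 1, 4 or 5, 1 pan-epithelial member fell, as RAB25, lower by 0.67 ± 0.22 with all libraries, then did not pass (adjusted p from 0.0513 to 0.0744). The keratin gene KRT7 rose by 3.60 ± 0.29 and KRT18 by 1.02 ± 0.15, the latter with 75.5% of its windows unique, and GRHL2, an epithelial transcription factor, fell by 0.72 ± 0.17. The mean log2 CPM of the list was 0.52 higher in mid-secretory libraries (exact permutation p = 0.0152), and FOXA2 minus that mean differed by -0.78 (exact permutation p = 0.0195), a test chosen after the values were seen. Most of that difference is the rise of the list mean, since FOXA2 itself differed by -0.26 (exact permutation p = 0.229). As the list members did not rise alike, it cannot be read as a fall of FOXA2 relative to epithelial content. HOX genes, which pattern the reproductive tract, had 1 of 26 higher (HOXB2), 4 lower and 21 not passing, or 1 and 3 adjusted over the list alone (camera adjusted p = 0.222), and 2 were higher without proliferative replicate 3 or mid-secretory replicate 5. HOXA10 fell by 0.91 ± 0.21 and HOXA11 by 0.78 ± 0.23; 76.8% and 71.0% of their windows were unique and 31.1% of HOXA11's exon bases overlap a gene on the other strand. The ciliated cell list had 0 of 24 higher, 1 lower and 23 not passing, the same adjusted over the list alone (camera adjusted p = 0.837), the lower gene being MCIDAS, a regulator of multiciliated cells, which fell by 4.19 ± 0.58 (4.81 without mid-secretory replicate 4).

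The hedgehog and WNT pathways, which carry signals between epithelium and stroma, were lower as sets. The hedgehog list had 2 of 14 higher, 8 lower and 4 not passing, the same adjusted over the list alone (camera adjusted p = 0.00541; adjusted p = 0.133 with an estimated correlation). The receptors PTCH2 and SMO fell by 3.12 ± 0.28 and 1.68 ± 0.13, and the ligand IHH, named after its values were seen, fell by 4.58 ± 0.42 from 286 ± 140 to 11.98 ± 4.74 CPM. GAS1, a co-receptor, rose by 1.79 ± 0.32 and the ligand SHH by 1.40 ± 0.35. The WNT list had 5 of 41 higher, 19 lower and 17 not passing (5 and 21 adjusted over the list alone; camera adjusted p = 0.00221; adjusted p = 0.0523 with an estimated correlation). DKK3 fell by 2.83 ± 0.21, and the WNT antagonist DKK1 rose by 7.86 ± 0.37 from 1.10 ± 0.539 to 257 ± 63.1 CPM. Several members that fell, among them SFRP4, WIF1 and DKK3, are known as WNT antagonists or relatives of them, so the list holds genes that act in both directions on the pathway. Of the hedgehog members 8 fell within title number 1 and 6 within title number 2, and of the WNT members 15 fell within each.

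Complement, metallothionein, steroid metabolism and tight junction genes were higher as sets. Of 25 complement genes 18 rose, 3 fell and 4 did not pass (20 and 3 adjusted over the list alone; camera adjusted p = 4.47e-08; adjusted p = 0.00794 with an estimated correlation). SERPING1, the C1 inhibitor, rose by 3.66 ± 0.19 from 103 ± 29.3 to 1306 ± 156 CPM, while CFH, an inhibitor of the alternative pathway, fell by 1.27 ± 0.33 and the terminal component C5 by 0.81 ± 0.18. Metallothioneins, small zinc and copper binding proteins, together with a zinc exporter, had 8 of 10 higher, 0 lower and 2 not passing, the same adjusted over the list alone (camera adjusted p = 2e-06; adjusted p = 0.19 with an estimated correlation). Without proliferative replicate 1, 1 of this list fell. MT1H rose by 8.64 ± 0.41 and MT1M by 5.84 ± 0.32. Steroid metabolism had 9 of 18 higher, 1 lower and 8 not passing (10 and 1 adjusted over the list alone; camera adjusted p = 0.00493; adjusted p = 0.0523 with an estimated correlation). Without mid-secretory replicate 1, 5 of these were higher, and without proliferative replicate 5, 2 were lower. HSD17B2, which inactivates oestradiol, rose by 5.12 ± 0.28 from 1.69 ± 0.753 to 59.1 ± 15.2 CPM, and SRD5A3 by 2.53 ± 0.18. The single fall was that of HSD11B2, by 1.04 ± 0.32, a call lost without mid-secretory replicate 4 (adjusted p = 0.0519) or 5 (adjusted p = 0.0527). Mucins and tight junction genes had 12 of 21 higher, 0 lower and 9 not passing (14 and 0 adjusted over the list alone; camera adjusted p = 0.000145; adjusted p = 0.198 with an estimated correlation), with the claudins CLDN4 up by 3.45 ± 0.21 and CLDN1 by 2.70 ± 0.24, and 1 lower without proliferative replicate 4. The mean of the pan-epithelial marker list was also higher, by 0.52 (exact permutation p = 0.0152).

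In other functional lists the members went both ways and camera did not pass, although prostaglandin and retinoid metabolism were higher by fry. Prostaglandin metabolism had 9 of 20 higher, 4 lower and 7 not passing, the same adjusted over the list alone (camera adjusted p = 0.113; fry adjusted p = 1.34e-07). The phospholipase PLA2G4F rose by 5.71 ± 0.45, while HPGD, which degrades prostaglandins, fell by 2.07 ± 0.41 and the prostaglandin transporter SLCO2A1 by 2.37 ± 0.44. Retinoid metabolism had 9 of 21 higher, 5 lower and 7 not passing (9 and 6 adjusted over the list alone; camera adjusted p = 0.222; fry adjusted p = 5.01e-05). The retinol carrier RBP4 rose by 7.10 ± 0.40 and the retinal reductase DHRS3 by 2.82 ± 0.19, and the retinoic acid binding protein CRABP2 fell by 3.49 ± 0.32. Ion and water transport had 9 of 28 higher, 9 lower and 10 not passing (10 and 9 adjusted over the list alone; camera adjusted p = 0.85). The water channel AQP3 rose by 5.27 ± 0.42 and the kinase SGK1 by 2.90 ± 0.28, whereas the water channel AQP5 fell by 4.60 ± 0.41 and the sodium pump subunit ATP1B1 by 2.67 ± 0.32. Matrix metalloproteinases and inhibitors had 10 of 24 higher, 6 lower and 8 not passing (10 and 7 adjusted over the list alone; camera adjusted p = 0.661). The inhibitor TIMP3 rose by 3.94 ± 0.38 and ADAMTS1 by 3.03 ± 0.19, and the gland protease MMP7 fell by 4.32 ± 0.35 from 316 ± 131 to 15.8 ± 2.89 CPM. The median of this list was 0.38 and its mean -0.01, with an upward set direction.

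Markers of natural killer cells, the main lymphocytes of secretory endometrium, rose together. Of 29 markers 26 rose, 0 fell and 3 did not pass, the same adjusted over the list alone (camera adjusted p = 1.44e-08; adjusted p = 0.399 with an estimated correlation). The cytotoxic protease GZMB rose by 4.38 ± 0.54 from 3.46 ± 1.43 to 71.9 ± 63.7 CPM and the receptor KIR3DL1 by 3.47 ± 0.49, with 22 members higher within title number 1 and 19 within title number 2. GNLY, the cytotoxic protein granulysin and named after its values were seen, rose by 4.09 ± 0.61 from 115 ± 44.6 to 1959 ± 1833 CPM. Without mid-secretory replicate 1 the rises were 3.69 for GZMB, 2.83 for KIR3DL1 and 3.45 for GNLY. T cell markers had 2 of 21 higher, 3 lower and 16 not passing (1 and 3 adjusted over the list alone; camera adjusted p = 0.525). Of the T cell markers 1 was higher without proliferative replicate 2, 3, 4 or 6 or mid-secretory replicate 1, 4 or 5, and 4 without proliferative replicate 5. CD3E, a subunit of the T cell receptor complex that some natural killer cells also hold, rose by 1.80 ± 0.46 and the kinase ITK by 1.24 ± 0.43 (0.75 without mid-secretory replicate 1), the latter not passing without proliferative replicate 2, 3, 4 or 6 or mid-secretory replicate 1, 4 or 5 (adjusted p from 0.0607 to 0.168), and FOXP3, the regulatory T cell factor, and IL7R fell by 1.29 ± 0.30 and 1.66 ± 0.40. Macrophage and dendritic cell markers had 10 of 20 higher, 0 lower and 10 not passing (11 and 0 adjusted over the list alone; camera adjusted p = 0.00699; adjusted p = 0.709 with an estimated correlation), with CD14 up by 1.26 ± 0.27 and TYROBP, an adaptor also used by natural killer cells, by 1.88 ± 0.44. The count of higher macrophage and dendritic cell markers was 7 without proliferative replicate 3 or mid-secretory replicate 1 and 14 without mid-secretory replicate 2, and within the title numbers it was 4 and 6. By fry this list did not pass (adjusted p = 0.0852). B cell and plasma cell markers had 1 of 14 higher, 5 lower and 8 not passing, the same adjusted over the list alone (camera adjusted p = 0.325), with 0 higher without proliferative replicate 2 or 4 or mid-secretory replicate 1 and 2 higher without proliferative replicate 5. MZB1, a plasma cell gene, rose by 1.40 ± 0.44 (0.79 without mid-secretory replicate 1), a call lost without proliferative replicate 2 or 4 or mid-secretory replicate 1 (adjusted p from 0.0542 to 0.115). The antibody gene IGHG1 fell by 4.72 ± 0.95 (5.48 without mid-secretory replicate 2) and DERL3 by 2.33 ± 0.46, but only 45.6% and 33.0% of their windows were unique and 77.0% of DERL3's exon bases overlap a gene on the other strand. Within title numbers 1 and 2, IGHG1 fell by 2.92 ± 0.95 and 6.70 ± 0.36. Mast cell and neutrophil markers had 4 of 11 higher, 3 lower and 4 not passing (5 and 3 adjusted over the list alone; camera adjusted p = 0.663; median -0.52, mean 0.48, set direction upward), with 1 lower without proliferative replicate 1, 3 or 5 or mid-secretory replicate 2 or 3. The neutrophil genes CSF3R and S100A9 rose by 3.97 ± 0.56 and 3.48 ± 0.40, CSF3R by 2.84 without mid-secretory replicate 1, and KIT, the mast cell growth factor receptor, fell by 1.54 ± 0.22 and HDC, which makes histamine, by 1.34 ± 0.41, a call lost without mid-secretory replicate 2 (adjusted p = 0.0576) or 3 (adjusted p = 0.0550) and not tested without proliferative replicate 1, 2, 3, 5 or 6.

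**Figure D4:**
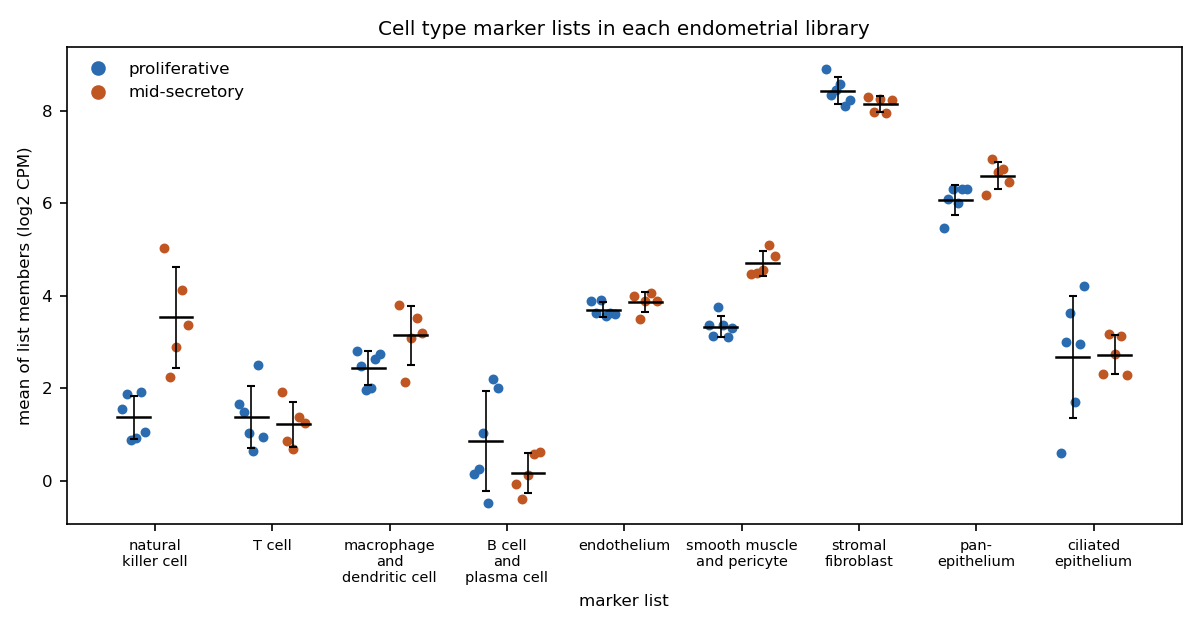
Mean log2 CPM of the members of each cell type marker list in the 6 proliferative and 5 mid-secretory libraries, with points for libraries and bars for the mean and SD. The natural killer list was 2.16 higher in mid-secretory libraries, whereas the T cell list differed by -0.16.

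Smooth muscle and pericyte markers were higher as a set, while the set tests of stromal fibroblast and endothelial markers did not pass. Stromal fibroblast markers had 6 of 20 higher, 8 lower and 6 not passing, the same adjusted over the list alone (camera adjusted p = 0.605). PDGFRA rose by 1.59 ± 0.21 and the matrix proteoglycan VCAN by 1.30 ± 0.24, while the matrix genes POSTN and ECM1 fell by 4.63 ± 0.62 and 2.06 ± 0.24. Smooth muscle and pericyte markers had 9 of 18 higher, 1 lower and 8 not passing, the same adjusted over the list alone (camera adjusted p = 0.00405; adjusted p = 0.24 with an estimated correlation). MYOCD, the master coactivator of smooth muscle genes, rose by 6.14 ± 0.34 from 0.693 ± 0.384 to 49.1 ± 12.96 CPM and LMOD1 by 2.86 ± 0.26, while NOTCH3, a receptor of pericytes, fell by 0.46 ± 0.12, and 2 were lower without proliferative replicate 5. Endothelial markers had 2 of 19 higher, 1 lower and 16 not passing, the same adjusted over the list alone (camera adjusted p = 0.671). LYVE1, a lymphatic marker, rose by 1.57 ± 0.30 and EMCN by 0.68 ± 0.18, and ERG fell by 0.60 ± 0.18, a call lost without mid-secretory replicate 2 (adjusted p = 0.0519) or 5 (adjusted p = 0.0532), while 2 were lower without proliferative replicate 5. Blood markers had 3 testable members, 0 higher, 0 lower and 3 not passing, the same adjusted over the list alone (camera adjusted p = 0.952; median -0.39, mean -0.45, set direction upward; 1 lower without any one of the mid-secretory libraries), and the haemoglobin gene HBB stood at 71.5 ± 69.2 and 67.0 ± 56.5 CPM. Squamous markers had 5 testable members, 3 higher, 2 lower and 0 not passing, the same adjusted over the list alone (camera adjusted p = 0.325; higher by fry, adjusted p = 0.00477), with SFN up by 3.01 ± 0.29, KRT15 by 2.54 ± 0.38 and PKP1, named after its values were seen, by 1.94 ± 0.53. The lower squamous markers were KRT5, by 2.11 ± 0.77, a call lost without proliferative replicate 2, 3, 4 or 5 or mid-secretory replicate 1, 4 or 5 (adjusted p from 0.0573 to 0.124), and KRT13, by 1.93 ± 0.65 (2.56 without mid-secretory replicate 2), a call lost without proliferative replicate 2 or 3 or mid-secretory replicate 3, 4 or 5 (adjusted p from 0.0536 to 0.0770).

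The list of immediate early and heat shock genes, which respond to stimulation and tissue handling, was higher as a set. It had 9 of 22 higher, 2 lower and 11 not passing (10 and 2 adjusted over the list alone; camera adjusted p = 0.00587; adjusted p = 0.0721 with an estimated correlation). ZFP36, which destabilises inflammatory mRNAs, rose by 2.41 ± 0.16, the phosphatase DUSP1 by 1.82 ± 0.14, and the chaperone HSPH1 fell by 0.62 ± 0.18. NR4A2, an immediate early gene, fell by 0.70 ± 0.25, a call kept only without proliferative replicate 1 or mid-secretory replicate 1 (adjusted p otherwise from 0.0520 to 0.108). Of this list 1 was lower without proliferative replicate 2, 4, 5 or 6 or mid-secretory replicate 2, 3, 4 or 5. Mitochondrially encoded mRNAs took 9.77% ± 3.55 (SD, n = 6) of proliferative and 11.7% ± 2.19 (SD, n = 5) of mid-secretory counts, a difference within the spread (exact permutation p = 0.294). Of these 13 mRNAs 1 rose, 0 fell and 12 did not pass (0 and 0 adjusted over the list alone), and the set test passed (camera adjusted p = 0.0392; adjusted p = 0.73 with an estimated correlation). The 1 rise, MT-ND6 by 0.92 ± 0.27, was lost without mid-secretory replicate 1 (adjusted p = 0.0622), and 6 rose without proliferative replicate 6. Cytosolic ribosomal protein mRNAs had 2 of 35 higher, 0 lower and 33 not passing (0 and 0 adjusted over the list alone; camera adjusted p = 0.02; adjusted p = 0.771 with an estimated correlation). Of these, 1 was higher without proliferative replicate 2, 4 or 6 or mid-secretory replicate 1, 3 or 5, 5 without proliferative replicate 5 and 7 without mid-secretory replicate 2. RPS18 rose by 0.55 ± 0.18, a call lost without proliferative replicate 2, 4 or 6 or mid-secretory replicate 1, 3 or 5 (adjusted p from 0.0535 to 0.104). RPL10, at 0.48 ± 0.14, had 47.1% unique windows and 52.7% of its exon bases overlapped a gene on the other strand. The mitochondrial set call was lost without proliferative replicate 1 (adjusted p = 0.0502), 3 (0.122) or 4 (0.141) or mid-secretory replicate 1 (0.1) or 3 (0.072), and its direction turned within title number 2 (adjusted p = 0.14). It was also lost with title number as a covariate (0.0542), under a stricter expression filter (0.0649) and by fry (0.158). The ribosomal set call was lost without proliferative replicate 4 (adjusted p = 0.141) or mid-secretory replicate 1 (0.126) or 3 (0.0608), within title number 2 (adjusted p = 0.391) and by fry (0.177). Nuclear retained and depletion escape RNAs had 2 of 9 higher, 0 lower and 7 not passing, the same adjusted over the list alone (camera adjusted p = 0.212; higher by fry, adjusted p = 0.0175; 4 higher without proliferative replicate 6 and 1 lower without proliferative replicate 3), the nuclear RNAs MALAT1 and NEAT1 rising by 1.27 ± 0.13 and 1.57 ± 0.23. In all, 13 of the 34 lists were higher and 4 lower by camera, and with an estimated correlation 3 stayed higher (receptivity, decidualization and complement) and 1 lower (oestrogen-responsive genes).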

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

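The gap test used here was fixed before the data were examined: within each phase, the distance of the highest or lowest library to its nearest neighbour was divided by the range of the group and compared with Dixon's 95% critical value. It was applied to 314 groups of values, 157 measures in each phase, and 13 stood out, where chance alone gives about 5% of groups, or 15.7. No pattern is therefore read into them, and each is given as a value on the log2 CPM scale.

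In the proliferative group, MMP7 was low in replicate 3 (6.56, others 8.09 to 8.93; gap ratio 0.647). AQP3 was high in replicate 5 (3.60, others 2.09 to 2.42; gap ratio 0.780). LYVE1 was high in replicate 1 (1.10, others -0.28 to 0.19; gap ratio 0.660). Replicate 1 also had the lowest mean of the pan-epithelial marker list (5.47, others 6.00 to 6.30; gap ratio 0.630). Its mean of the immediate early and heat shock list was lowest as well (4.14, others 4.26 to 4.30; gap ratio 0.711). Replicate 4 had the lowest mean of the cytosolic ribosomal protein list (9.43, others 9.87 to 10.07; gap ratio 0.694).

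In the mid-secretory group, HIST1H1C was low in replicate 2 (4.12, others 4.61 to 4.79; gap ratio 0.738) and FOXP3 was high in the same library (-0.43, others -1.42 to -1.22; gap ratio 0.798). DAPL1 gave a gap ratio of 1 because replicate 2 held the only 2 reads of the group, at the floor. SLC1A1 was low in replicate 3 (8.73, others 9.04 to 9.13; gap ratio 0.759). CSF3R was high in replicate 1 (6.63, others 3.39 to 4.31; gap ratio 0.717). MMP7 was low in replicate 5 (3.46, others up to 4.22; gap ratio 0.7105), and so was the mean of the WNT list (2.83, others 3.03 to 3.08; gap ratio 0.813).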

How the results depend on the processing

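The library sizes without mitochondrially encoded genes were chosen after the data were seen; all other alternatives were planned. FOXA2 was below 0 and was not called in any setting. Its adjusted p ran from 0.0930 to 0.858. The counts of genes stayed within 1.5 times of 3767 higher and 3687 lower, with 2 exceptions. Title number 2 alone gave 2117 and 1986 (fewer libraries), and a 2-fold minimum gave 2120 and 2200 (a stricter rule). Over the fits with all other settings they ran from 2730 and 2575 (title number 1 alone) to 4266 and 4473 (DESeq2), and without each library from 3248 to 3664 and from 3271 to 3705. In each setting 0 of the genes called in the main comparison were called in the opposite direction. Of the 34 lists, 13 were higher and 4 lower. An estimated correlation gave 3 and 1, and title number 2 alone gave 11 higher and 8 lower; the cause was not tested. Without each library the lists numbered 11 to 13 higher and 4 lower. Of 118 named genes called, at least 94 kept their call and direction in each setting, the fewest in title number 2 alone, and 109 to 116 without each library.

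Directions turned only for results that had not passed, except 1 call, and the cause was not tested. HBB changed from -0.10 to 0.27 with title number as covariate, 0.92 within title number 1, and -0.66 to 0.45 without 1 library, and HBA2 from -0.87 to 0.79 within title number 1 and -1.68 to 0.49 without 1 library. Only 18.6% of the windows of HBA2 are unique. List directions turned, with these adjusted p, for ciliated markers under the stricter filter (0.930), within title number 1 (0.406) and without proliferative replicate 3 or 6 or mid-secretory replicate 1 or 5 (0.587 to 0.924; 0.202 to 0.924 without each library in turn), and for T cell markers under that filter (0.930). Blood markers turned with the covariate (0.970), within title number 2 (0.0253) and without 1 library (range 0.569 to 0.924), and endothelial markers within title number 1 (0.770). Within title number 2, ion and water transport (0.996) and stromal markers (0.758) turned, as did mitochondrially encoded mRNAs (0.1396), the 1 list that had passed. Among the named genes and single lists, 2870 values kept their direction and side of the threshold, 119 lost and 10 gained a call, and 29 turned. Depth limits the folds of genes with few reads in 1 phase, such as GAST. In the simulation the test found 5.97% of 1.5-fold changes. Only 200 genes were changed there, far fewer than were called here, which makes the adjusted threshold stricter. That rate therefore does not give the share of small changes found in these data.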

Other observations

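All tests in this part were chosen after the results were seen, except the count of other splits of the libraries, which was planned. Protein-coding genes were grouped by the letters that open their symbols. The 114 families with at least 15 tested members were tested for an excess of higher or lower genes with 1-sided Fisher's exact tests. Adjustment was by Benjamini-Hochberg over families, separately for each direction. These tests treat genes as independent, although members of a family can move together, so their p-values do not measure the spread between samples. Families passed in 2 cases as higher and in 3 as lower. Kinesins, the motors of microtubule transport and mitosis, had 22 of 39 members lower and 7 higher (adjusted p = 3.53e-05). Nucleoporins, which build the nuclear pore, had 11 of 21 lower and 0 higher (adjusted p = 0.0408), and centrosomal CEP genes 15 of 35 lower and 2 higher (adjusted p = 0.0462). The S100 calcium-binding proteins with the S1PR receptors had 14 of 20 higher and 1 lower (adjusted p = 0.000273). In that family S100P rose by 9.03 (7.99 without mid-secretory replicate 2), S100A3 by 4.60, S100A6 by 2.79 and S100A10 by 2.75. Interleukins and their receptors had 22 of 54 higher and 8 lower (adjusted p = 0.0300), where IL1B rose by 5.02, IL6ST by 2.51 and IL1R1 by 2.08, and IL17RB fell by 2.64. Collagen genes, with 16 of 41 lower and 7 higher, did not pass (adjusted p = 0.0761).

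Non-coding genes changed as well. Of 1239 tested lincRNA genes 176 rose and 220 fell, and of 1360 antisense genes 143 rose and 222 fell. LINC01502 (chromosome 9, 135574935 to 135587112) rose by 10.32 ± 0.49 (SE), from 0.120 ± 0.131 CPM (SD, n = 6) to 156 ± 59.6 CPM (SD, n = 5). LINC02532 (chromosome 6, 106717452 to 106787541) rose by 8.92 ± 0.48, from 0.157 ± 0.0930 to 77.3 ± 37.5 CPM. Because the strand setting of the counting is not known, antisense genes cannot be separated from the genes they overlap. A separate comparison of title numbers, with phase in the model, called 41 genes, all higher in title number 2. Of these 25 were pseudogenes, against 9.65% of the genes tested (Fisher's exact test, odds ratio 14.8, p = 7.96e-16), and 3 of the 41 were also called between phases. This test too treats genes as independent, so its p-value does not measure the spread between libraries.

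The number of genes that differed between phases was set against other splits of the 11 libraries into 6 and 5. Of 100 splits drawn, 1, the real one, gave as many as 3767 genes higher, and the highest other split gave 1511. For genes lower, 1 split, again the real one, gave 3687, and the highest other gave 2300. The smallest share that 100 splits can give is 1 in 100. Every other split mixes the phases, so the phase difference widens the spread within its groups and lowers its counts. The comparison therefore cannot exclude chance by itself. The split with the highest other counts set all 5 mid-secretory libraries and 1 proliferative library against the 5 others, so it followed the phases almost fully. In it the 5 proliferative libraries took the place of the mid-secretory group. Its 1511 genes were thus higher, and its 2300 lower, in those proliferative libraries, the reverse of the real split. Either way both counts lay below those of the real split.

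Replication-dependent histone mRNAs, which lack a poly(A) tail, stood near 0 beside abundant mRNAs of dividing cells, although the labels name ribosomal RNA depletion. In proliferative libraries the 28 histone genes had a median of 0.0571 CPM, and 24 lay below 1 CPM, while the 35 cell cycle genes had a median of 61.3 CPM. Loss of reads that fit several histone genes was argued against: 24 of the 28 have mostly unique sequence, and their median was also 0.0571 CPM. Libraries of mostly polyadenylated RNA cannot be told apart from a loss of short or structured RNA: of 54 other genes whose RNAs lack a tail or largely lack one, 53 had a mean below 1 CPM, most of them small Cajal body RNA genes, with 4 reads of TERC and 0 of RMRP, RPPH1 and RN7SK over all libraries, but the mitochondrial mRNA MT-ND6 was abundant, at 1.35e+06 reads. Sequence shared with other genes was not searched for these 54 genes, MT-ND6 apart. Reads left uncounted because they fit several genes therefore stay possible for them. No biological explanation was tested.

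Of 18 smooth muscle and pericyte genes 9 rose, 1 fell and 8 did not pass (camera adjusted p = 0.00405; adjusted p = 0.24 with an estimated correlation). MYOCD was up by 6.14, LMOD1 by 2.86 and DES by 3.59, whereas ACTG2, CNN1, ACTA2 and SYNM did not pass. More vessel wall cells cannot be told apart from other sources, since the 8 markers of such cells in the list went both ways around a median of -0.25: RGS5, NOTCH3, CSPG4, MCAM and HIGD1B lay between -0.48 and -0.17, while STEAP4 rose by 4.43, KCNJ8 by 1.46 and ABCC9 by 1.44. Muscle wall tissue taken with the biopsies cannot be told apart from a change within the endometrium either. ACTG2, abundant in uterine muscle, reached 4.10 CPM in its highest mid-secretory library, below the lowest mid-secretory MYOCD level of 34.1 CPM. CNN1 averaged 24.6 CPM in mid-secretory libraries but reached 68.4 CPM in 1 of them. Muscle tissue was predicted to make both genes gain more CPM than MYOCD. That was not seen, as ACTG2 gained 0.744 and CNN1 12.5 CPM against 48.4 for MYOCD. TAGLN and LMOD1, however, gained more than MYOCD, by 143 and 95.5 CPM. A change of expression in stromal cells with the phase may also contribute and was not tested.

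Natural killer cell genes rose in mid-secretory biopsies, with a list mean 2.16 higher (exact permutation p = 0.00216, the smallest the libraries can give). A gain of all leukocytes alike, or a lower share of the main cell type, would raise T cell markers alike, but the difference between the natural killer and T cell list means moved by 2.32 (exact permutation p = 0.00216). The T cell mean itself moved by -0.16 (exact permutation p = 0.677). A single library as the source was also argued against, since at least 24 of the members stayed higher without each library in turn. A gain of several kinds of leukocyte other than T cells stays open. Of 20 macrophage and dendritic cell markers 10 were higher and 0 lower (camera adjusted p = 0.00699, or 0.709 with an estimated correlation, and fry adjusted p = 0.0852). The neutrophil genes CSF3R and S100A9 rose by 3.97 (2.84 without mid-secretory replicate 1) and 3.48. More natural killer cells, or more expression in each such cell, may each be the source, and bulk libraries do not separate them.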
